A study of Mus musculus with 8 samples.

How the data were processed

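RNA sequencing of total liver RNA was analysed from 8 ob/ob mice, 4 given a control siRNA (NTC) and 4 given the siRNA Dgat2-1473, each at 10 mg/kg. Groups were taken from the treatment label of each sample, and the libraries are called control 1 to 4 and treated 1 to 4 after their column names, which match the sample titles. The labels describe separate mice, so p-values measure the spread between animals. No batch, date or cage is given in the sources used here.

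The deposited table holds RSEM expected counts per gene, that is, estimated read numbers in which a read matching several genes or transcripts is divided among them, and the authors had not scaled these values by depth or gene length, per the file headers and the values. Between 93.7% and 94.2% of the values of a library were whole numbers. Trimmomatic 0.11.8, STAR, RSEM 1.2.28, DESeq2 and the mouse build mm10 are named, per the submitters' processing notes, without their order or settings. Genes were quantified on gene models with RefSeq transcript accessions, per the file headers. The annotation version, the read length and whether counting used strand are not given in the sources used here, so overlapping and antisense genes could not be told apart. Values of genes in families with near-identical copies, such as the hemoglobin, serum amyloid A, amylase and acyl-CoA thioesterase genes, depend on how RSEM divided shared reads and are uncertain, whether or not this is repeated beside them.

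The table listed 23845 genes, all with a symbol, and every column of counts belonged to 1 of the 8 samples. Through their RefSeq accessions 23578 genes (98.9%) were matched to loci of the RefSeq annotation of GRCm38.p6, the assembly that mm10 represents, which gave the coordinates. Library totals ranged from 21263165 to 29761939 expected counts, and the 10 most abundant genes took 17% to 19.7% of each library, led by Alb in all 8. Replicates within a group differed by more than counting noise, with a chi-square per degree of freedom of 19.7 to 144 over the 12 pairs, so that no library was a copy of another.

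Expected counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16. Genes with too few counts were removed by filterByExpr (minimum count 10, minimum total 15), which left 13820 genes. Libraries were scaled by the trimmed mean of M values (TMM), with factors from 0.919 to 1.083, and CPM values are counts scaled by the effective library size, as edgeR computes them. The main test was the quasi-likelihood F test for treatment, two-sided, with no covariate, and genes with a Benjamini-Hochberg adjusted p below 0.05 were called changed. The words rose and fell are used only for such genes. Fold changes are treated over control, errors are standard errors of the fit for log2 fold changes and standard deviations over 4 libraries for CPM, and a p of a named gene is the edgeR adjusted p. The common dispersion was 0.0378, a biological coefficient of variation of 0.195. With 4 libraries against 4, an exact permutation test over the 70 assignments cannot go below p = 0.0286. On simulated counts for the Dgat2 siRNA against control comparison (13698 genes, 200 of them changed) the edgeR script recovered 19.4% of genes changed by 0.5 on the log2 scale, 76.1% of those changed by 1 and 95.5% of those changed by 2. Of its calls 5.93% were false, against 22.5% with DESeq2. Far fewer genes changed in this simulation than in the data, so these shares need not carry over.

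Before the data were examined, 34 gene lists were fixed for pathways of liver lipid, sterol, bile acid, glucose and drug metabolism, for stress, injury, inflammation, fibrosis and the cell cycle, for cell types that a piece of liver can hold (hepatocytes by zone, Kupffer cells, neutrophils, lymphocytes, stellate, endothelial and bile duct cells, adipocytes, red cells, pancreas or gut), and for checks of handling, time of death and sex. Of their 654 entries 649 were found, 9 of them under another symbol in the table (Emr1 for Adgre1, Agpat9 for Gpat3). Lists with at least 5 tested genes (32 lists) were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) at a preset inter-gene correlation of 0.01, two-sided, with adjustment over the 32 lists, and again with the correlation estimated from the residuals. Camera asks whether the genes of a list rank apart from all other genes. For each list the number of changed genes is given after adjustment over all genes tested and adjusted over the list alone.

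The genes named were fixed by a rule set at the same time. It took Dgat2 and Dgat1. It took the 10 largest rises and 10 largest falls among changed genes with a mean CPM of at least 5 and groups that do not overlap, leaving out unnamed gene models. It took up to 4 changed genes per list by size of fold change, or up to 2 of the most abundant where none changed. Srebf1, Fasn, Scd1, Cpt1a, Cd36, Plin2, Apob, Col1a1, Acta2, Tnf and Trem2 were always taken. It gave 126 genes. Other genes are named where they belong to a fixed list, and were then chosen after their values were seen.

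Alternatives fixed in advance were the DESeq2 size factors in edgeR (RLE), no filter on low counts, a filter at a mean CPM of 5, the DESeq2 1.42.0 Wald test, limma voom with sample quality weights, unrounded counts, the replicate number as a block, a prior count of 0.5 for camera and each library left out in turn. The fit without control 3 and treated 1 together was added after seeing the data. After the results had been seen, 6 more gene lists were written, and 3' UTRs of GENCODE vM21 transcripts were searched for 7-mers of the Dgat2 transcript. Isoforms and the reads themselves were not analysed here.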

Results

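Liver transcripts were measured by RNA sequencing in 8 obese, leptin-deficient ob/ob mice that ate the GAN diet for 3 weeks, a feed rich in fat, fructose and cholesterol that is used to bring on steatohepatitis. At 10 weeks of age, 4 mice had received a control siRNA with no intended target and 4 the siRNA Dgat2-1473, both under the skin at 10 mg/kg. The Dgat2 siRNA carries N-acetylgalactosamine (GalNAc), a sugar that hepatocytes take up through the asialoglycoprotein receptor. The treatment label of the control siRNA names no such sugar. If the control lacks it, the groups differ in this sugar as well as in the target. The libraries held 21263165 to 29761939 expected counts each, and 15723 to 16201 genes were detected per library. The first principal component of log2 CPM took 55.1% of the variance and separated the groups. Treated 1 lay at 6.4 on it, between the other treated libraries (34.8 to 53.3) and the controls (-44.4 to -22.1). Control 3 stood apart on the second component (15.6% of the variance) at -44.6, against -3.8 to 15.1 in the other controls.

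**Figure D1:**
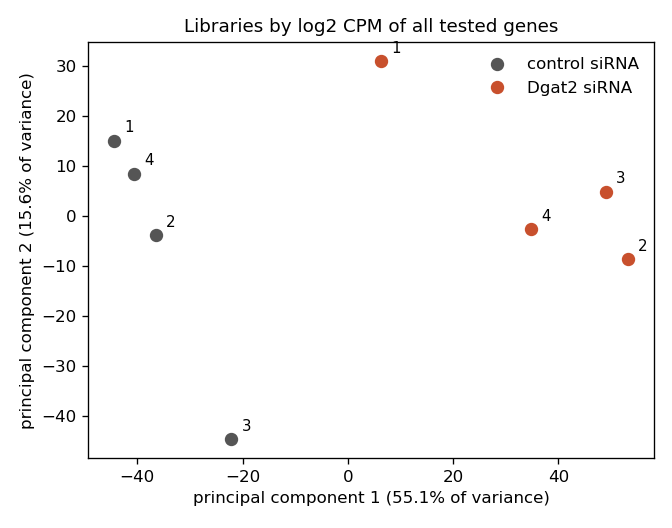
Position of the 8 liver libraries on the first and second principal components of log2 CPM over all tested genes; each point is 1 mouse, its number is the replicate number, and the colour is the siRNA. The groups separate on component 1 (55.1% of variance), with treated 1 at 6.4 nearest to the controls and control 3 at -44.6 on component 2.

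The comparison asks which liver transcripts differ when Dgat2 is silenced in hepatocytes. Dgat2 encodes diacylglycerol O-acyltransferase 2, which joins a fatty acyl chain to diacylglycerol in the last step of triglyceride synthesis. The gene lies on chromosome 7 of mm10, from 99153663 to 99182713 on the minus strand in RefSeq. Its mRNA fell from 647 ± 14.8 CPM in controls to 39.2 ± 7.73 CPM in treated livers (SD, n = 4 each), a log2 fold change of -4.04 ± 0.15 (SE, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.93e-06). The level left was 6.07% of control (95% confidence interval 4.79% to 7.68%), with 15024 to 18511 counts per control library and 826 to 1247 per treated library, in accord with the treatment label of each library. An exact permutation test of log2 CPM gave p = 0.0286, the smallest that 70 assignments allow. In the GENCODE transcript, of 8 exons and 2262 nucleotides, the 3' UTR starts at position 1375. If the number 1473 in the name of the siRNA counts along this transcript, which the labels do not say, the target site lies in the 3' UTR, in the last exon (99153658 to 99154700 in GENCODE). Dgat1, the other enzyme of this step, also fell, from 35.4 ± 4.21 to 24.2 ± 1.84 CPM (log2 fold change -0.55 ± 0.10 SE, edgeR adjusted p = 0.00511), which left 68.4% of control (95% confidence interval 58.3% to 80.1%).

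Beyond the target, many transcripts differed. Of 13820 genes tested 3411 (24.7%) changed, Dgat2 and Dgat1 among them, with 1715 higher and 1696 lower at an edgeR adjusted p below 0.05. The rise was at least 1 on the log2 scale in 520 genes and the fall in 319; 47 rose and 23 fell by at least 3. The groups did not overlap in 2865 of the 3411 genes, and among all tested genes 26.4% had groups that did not overlap, where chance gives 2.86%. The count changed with the libraries left out and with the test. It was 2060 without control 2, 2152 without control 4, 2208 without treated 2 and 2148 without treated 3, and 4818 without treated 1. The number that fell was also lower without control 1 (1126). With limma voom and quality weights it was 5576, and without control 3 and treated 1 together, a choice made after seeing the data, it was 5859.

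Among changed genes of mean CPM 5 or more, the largest rises were in Amy2a5, Fmo3 and Tmc5, all below 1 CPM in control livers on average. Fmo3, a flavin monooxygenase that makes trimethylamine N-oxide and is low in male mouse liver, went from 0.234 ± 0.0877 to 237 ± 118 CPM (log2 fold change 9.94 ± 0.61 SE, edgeR adjusted p = 2.9e-05). Amy2a5, a pancreatic amylase, went from 0.166 ± 0.0696 to 339 ± 222 CPM (log2 fold change 10.99 ± 1.02 SE), an uncertain value because amylase copies share reads. Afp, the fetal serum protein alpha-fetoprotein, rose by 5.57 ± 0.85 on the log2 scale, from 89.7 ± 81.7 to 4269 ± 2260 CPM, and the cell-surface proteoglycan gene Gpc3 by 4.80 ± 0.65. Tmc5 rose by 6.34, Bex1 by 5.02, the organic anion transporter gene Slc22a7 by 4.28, the estrogen sulfotransferase gene Sult1e1 by 4.16, the steroid dehydrogenase gene Hsd17b6 by 4.01 and the aldo-keto reductase gene Akr1b7 by 3.79. Treated 1 had the lowest level of the treated libraries for Amy2a5 (33.4 CPM), Fmo3 (72.7 CPM) and Afp (1276 CPM). The largest falls besides Dgat2 were in Chrna4, a nicotinic receptor subunit (log2 fold change -6.03 ± 0.74 SE), Ugt1a5 (-5.25), Serpina1e (-5.06), Sqle (-4.55), Pcsk9 (-4.55), Fdps (-4.08), Akr1c18 (-3.89), Fads1 (-3.86) and Lad1 (-3.53). Ugt1a5 shares exons with the other Ugt1a genes and Serpina1e has close copies, so both values are uncertain. Each of these 19 genes also passed the threshold in all 8 fits that left out 1 library.

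**Figure D2:**
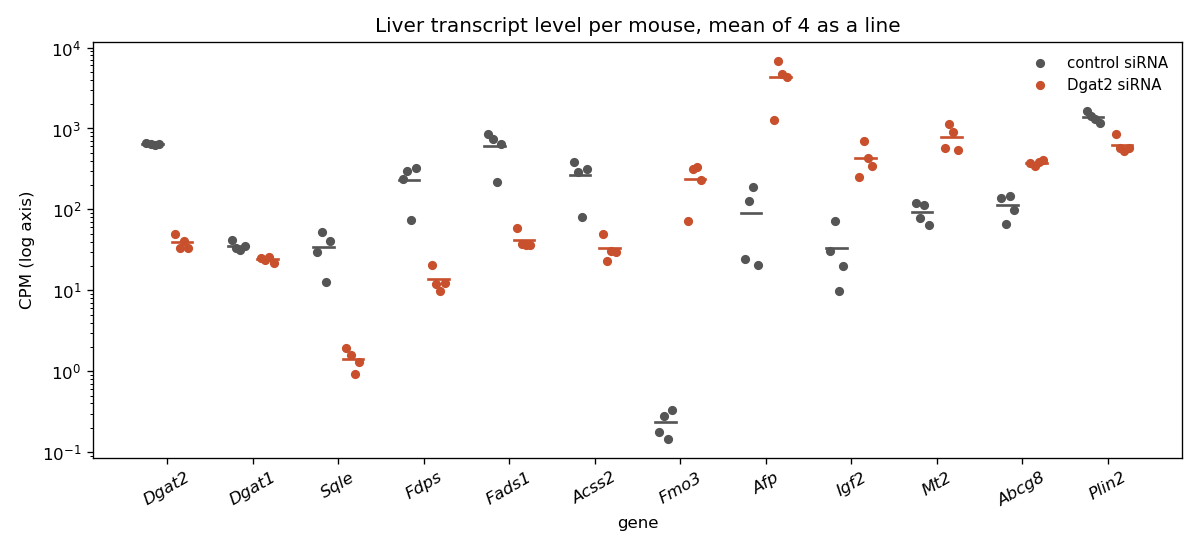
CPM (log axis) of 12 named genes in each of the 4 control (grey) and 4 treated (orange) livers; each point is 1 mouse and each line the mean of 4. Dgat2 falls from 647 to 39.2 CPM, while Fmo3 climbs from 0.234 to 237 CPM and control 3 has the lowest control level of Sqle, Fdps, Fads1 and Acss2.

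Cholesterol synthesis genes and other targets of the sterol-regulated transcription factor SREBP2 fell together. All 25 genes of the list fell, and all 25 passed when adjusted over the list alone (median log2 fold change -1.65). Sqle, squalene epoxidase, went from 33.9 ± 16.8 to 1.44 ± 0.432 CPM and Fdps, farnesyl diphosphate synthase, from 234 ± 113 to 13.8 ± 4.88 CPM. Idi1, an isomerase of the same pathway, fell by 3.32, Pcsk9, which sends the LDL receptor to degradation, by 4.55, Ldlr, the LDL receptor, by 1.38, Hmgcr, the rate-limiting reductase, by 1.09 and Srebf2 itself by 0.72 on the log2 scale. The list passed camera downward (adjusted p = 5.68e-16), and adjusted p = 0.757 with an estimated correlation, which was 0.73 between its genes. Control 3 had the lowest control level of Sqle (12.7 CPM against 29.9 to 52.4) and Fdps (73.1 against 237 to 323).

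Most genes of fatty acid synthesis and desaturation fell as well. Of 22 genes, 19 fell and 3 did not pass, and 21 were lower when adjusted over the list alone (median log2 fold change -1.69). The desaturases of polyunsaturated fatty acids Fads1 (612 ± 278 to 42.2 ± 11.6 CPM) and Fads2 (659 ± 210 to 90.8 ± 23.9 CPM) fell by 3.86 and 2.86 on the log2 scale. Acss2, which makes acetyl-CoA from acetate, fell by 3.01, and Me1, malic enzyme, by 2.59. Fasn, fatty acid synthase, fell by 2.35 ± 0.58 SE (edgeR adjusted p = 0.0177), and Scd1, stearoyl-CoA desaturase, by 1.57 ± 0.51 SE (edgeR adjusted p = 0.0481). Both lost the call in some fits with a library left out, while the fold changes in those fits stayed similar. Over all 8 such fits the log2 fold change ranged from -3.199 to -2.099 for Fasn and from -2.235 to -1.321 for Scd1. The adjusted p of Fasn was 0.0516 without treated 3 (log2 fold change -2.10) and 0.0545 without treated 4 (-2.23). That of Scd1 was 0.115 without control 1, 0.0796 without control 2, 0.0994 without control 4, 0.111 without treated 2, 0.116 without treated 3 and 0.107 without treated 4, with log2 fold changes of -1.65 to -1.32. Treated 1 kept 1210 CPM of Fasn against 224 to 381 in the other treated livers. Srebf1, which encodes the lipogenic factor SREBP1, had a log2 fold change of -0.53 ± 0.20 SE (edgeR adjusted p = 0.0727), which passed without treated 1 (-0.75, adjusted p = 0.00346), with DESeq2 (adjusted p = 0.0263) and with limma voom (adjusted p = 0.00844). The list passed camera downward (adjusted p = 1.82e-09), and adjusted p = 0.757 with an estimated correlation. Sterol and lipogenic genes together had 44 of 47 members lower.

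**Figure D3:**
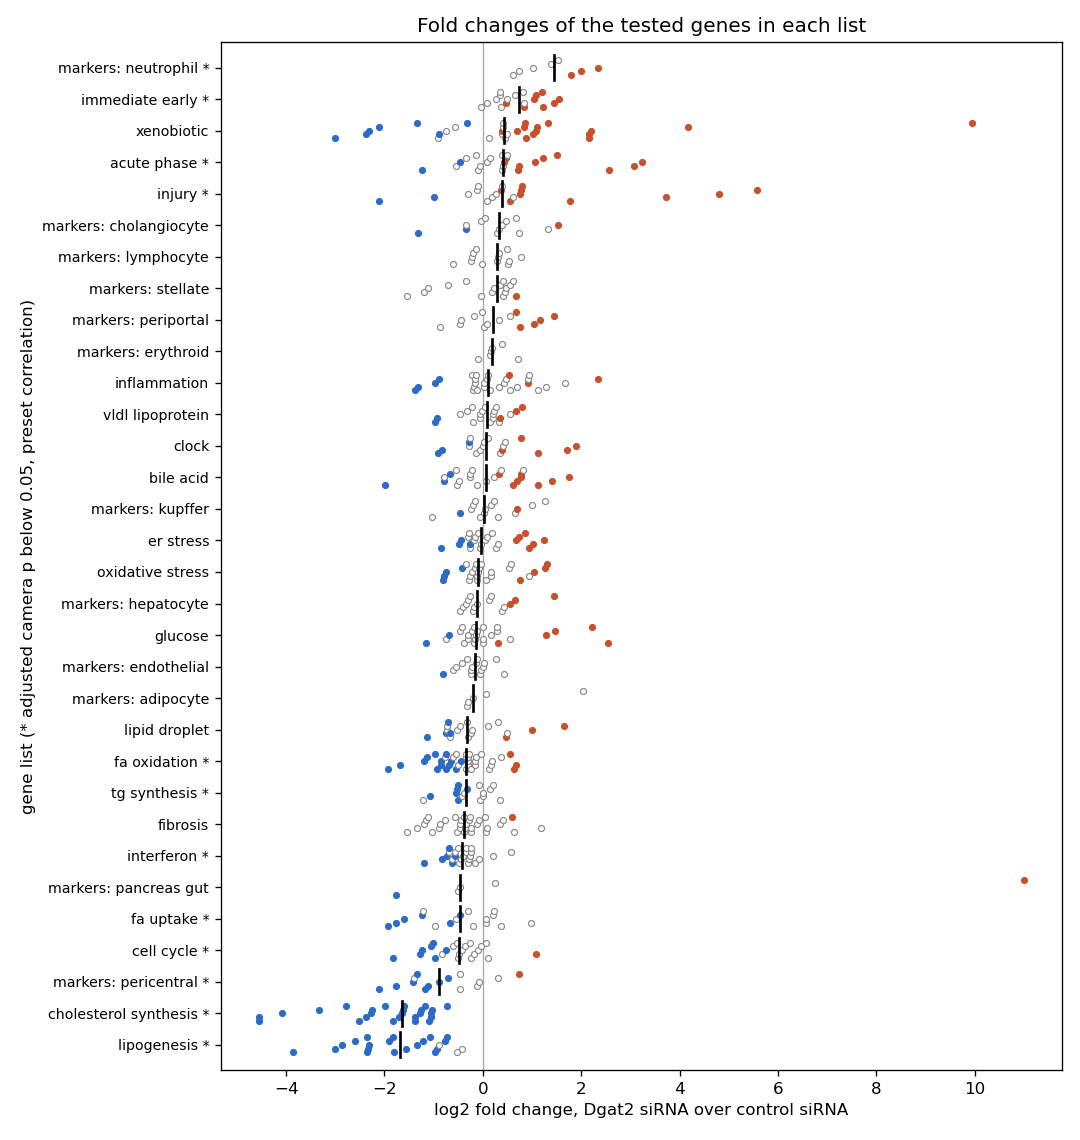
Log2 fold change (treated over control) of every tested gene in each of the 32 fixed lists tested with camera; filled red points rose, filled blue points fell, open points did not pass, and the black bar is the median of the list. The cholesterol synthesis and lipogenesis lists lie lowest, with medians of -1.65 and -1.69, and the asterisks mark the 12 lists past the camera threshold at the preset correlation.

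Some other enzymes of glycerolipid synthesis also fell. Of 16 genes, Dgat1 among them and Dgat2 not, 6 fell and 10 did not pass, with 7 lower when adjusted over the list alone. Gpam, which starts the pathway at the mitochondrial membrane, fell by 1.07, Agpat9 (Gpat3) by 0.53 and Lpin2, a phosphatidate phosphatase, by 0.50 on the log2 scale. Camera gave an adjusted p of 0.0455 downward, and adjusted p = 0.757 with an estimated correlation. The call ended without control 1 (adjusted p = 0.0651), control 4 (0.0532), treated 2 (0.0804) or treated 3 (0.0713), and 3 genes instead of 6 fell without control 1, 2 or 4 or treated 2, 3 or 4. Of 17 genes of fatty acid uptake, 6 fell and 11 did not pass, with 7 lower and 1 higher when adjusted over the list alone. Vldlr, a lipoprotein receptor, fell by 1.94, Fabp2, a fatty acid binding protein, by 1.77, and the acyl-CoA synthetases Acsl5 and Acsl1 by 1.61 and 1.23. The fatty acid translocase Cd36 had a log2 fold change of -0.19 ± 0.15 SE (edgeR adjusted p = 0.363). The uptake list passed camera downward (adjusted p = 0.0331), and adjusted p = 0.757 with an estimated correlation. In this list 1 gene rose without control 3 or treated 1, and 10 genes fell without the 2 libraries together.

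Among 19 genes of lipid droplets, 3 rose and 4 fell. Plin2, the main droplet coat protein of fatty liver, fell from 1381 ± 209 to 628 ± 146 CPM (log2 fold change -1.14 ± 0.18 SE, edgeR adjusted p = 0.00229), and Cideb, which acts in droplet and lipoprotein lipidation, by 0.75. Plin4, another coat protein, rose from 51.5 ± 11.3 to 161 ± 22.3 CPM (1.64 on the log2 scale), Hsd17b11 rose by 0.99 and the lipase gene Pnpla2 by 0.47. Camera gave adjusted p = 0.256; without treated 1 the list passed downward (adjusted p = 0.0433) with 10 genes lower, and without control 3 and treated 1 together (0.018) with 13. Over all 8 libraries the list had adjusted p = 0.924 with an estimated correlation. DESeq2 had 7 lower and limma voom 12. Adjusted over the list alone, 4 droplet genes were higher and 6 lower. Of 20 lipoprotein genes 3 rose and 2 fell, the same counts when adjusted over the list alone. Mttp, which loads lipid onto apolipoprotein B, fell by 0.98 and Sar1b, which acts in lipoprotein export, by 0.94, while Abca1 and Apoa5 rose by 0.79 and 0.67. Apob had a log2 fold change of -0.19 ± 0.15 SE (edgeR adjusted p = 0.357). Camera gave adjusted p = 0.672 for the lipoprotein list, and 4 of its genes were lower without treated 1.

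Genes of fatty acid oxidation were lower more often than higher. Of 37 genes, 14 fell, 3 rose and 20 did not pass, with 17 lower and 3 higher when adjusted over the list alone. The acyl-CoA thioesterases Acot1 and Acot2 fell by 1.93 and 1.68 on the log2 scale, Bdh1, which makes beta-hydroxybutyrate, by 1.13, and Acox1, which starts peroxisomal oxidation, by 0.97. Cyp4a31 and Cyp4a32, omega-hydroxylases with close copies whose values are uncertain, rose by 0.67 and 0.63, and Angptl4 by 0.55. Cpt1a, carnitine palmitoyltransferase 1A, had a log2 fold change of -0.27 ± 0.11 SE (edgeR adjusted p = 0.0892). It passed with DESeq2 (adjusted p = 0.0192), with limma voom (0.0216) and without treated 1 (0.0245). Camera passed downward (adjusted p = 6.31e-05), and adjusted p = 0.757 with an estimated correlation. The number that fell was 27 without treated 1, 7 without treated 3, 8 without treated 4 and 26 with limma voom.

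Bile acid and glucose genes went both ways. Of 23 bile acid genes 8 rose and 3 fell, also when adjusted over the list alone. The canalicular sterol transporters Abcg8 (112 ± 37.4 to 379 ± 23.5 CPM) and Abcg5 (165 ± 52.2 to 437 ± 38.7 CPM) rose by 1.75 and 1.41 on the log2 scale and the organic anion carrier gene Slco1a4 by 1.12, while Slc10a1, the bile acid uptake carrier, fell by 1.99. Camera gave adjusted p = 0.351. The number that fell was 7 without treated 1, 8 with limma voom and 1 without control 2 or treated 2, 3 or 4. Of 26 glucose and insulin response genes 5 rose and 2 fell, also when adjusted over the list alone. Igfbp2 rose by 2.55, Irs2, an insulin receptor substrate, by 1.46 and Ppp1r3c, which targets a phosphatase to glycogen, by 1.29, and Gck, glucokinase, fell by 1.16. The camera test gave adjusted p = 0.908; the median of the list was -0.13, its mean 0.14 and its camera direction upward. In this list 3 genes rose without control 2 or 4 or treated 3 or 4. Genes that fell numbered 6 without treated 1 and with limma voom, 11 without control 3 and treated 1 together, and 0 without control 1, 2 or 4 or treated 2, 3 or 4.

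Pericentral hepatocyte genes, those used around the central vein, were lower more often than higher. Of 15 genes 8 fell and 1 rose, with 9 lower and 1 higher when adjusted over the list alone (median log2 fold change -0.90). Cyp1a2 fell from 154 ± 10.1 to 35.5 ± 23.2 CPM, Rhbg, an ammonium transporter gene, by 1.77 on the log2 scale, Tbx3 by 1.42 and Glul, glutamine synthetase, by 1.11. Camera passed downward (adjusted p = 0.00612), and adjusted p = 0.757 with an estimated correlation; 5 genes fell without treated 3. Of 14 periportal genes 5 rose, with 6 higher and 2 lower when adjusted over the list alone. Cps1, the first enzyme of the urea cycle, rose from 1035 ± 176 to 2807 ± 149 CPM and Sds, serine dehydratase, by 1.15. By camera the list had adjusted p = 0.156, and 2 periportal genes fell without treated 1, with DESeq2 and with limma voom and 1 without control 3. Of 15 general hepatocyte markers 3 rose, 2 when adjusted over the list alone, and camera gave adjusted p = 0.827 (median log2 fold change -0.11, mean 0.10, direction upward). Only Cps1 held without control 2, 3 or 4 or treated 2, 3 or 4. Without treated 1 and with limma voom 5 of these markers fell, and 4 with DESeq2. The difference between the zones was not tested.

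Genes of drug metabolism changed often and in both directions. Of 30 genes 14 rose and 7 fell, with 15 higher and 7 lower when adjusted over the list alone. Besides Fmo3 and Sult1e1, Cyp1a1 rose by 2.21 on the log2 scale, Fmo2 by 2.16 and Cyp2c37 by 2.15, and Cyp2d9 fell by 2.32. Cyp2b9 and Cyp2b13, close copies of one another, had log2 fold changes of -2.37 (edgeR adjusted p = 0.024) and -3.01 (0.0268). With 1 library left out these ranged from -3.594 to -2.058 for Cyp2b9 and from -4.515 to -2.566 for Cyp2b13. Their calls ended without control 1 (adjusted p = 0.055 and 0.0717), treated 3 (0.0759 and 0.0784) or treated 4 (0.0604 and 0.0526), and for Cyp2b13 also without treated 2 (0.056). Cytochrome P450 genes of these subfamilies share sequence, so their values are uncertain. With camera the adjusted p was 0.0584. It passed upward with the RLE factors (0.0494) and without control 1 (0.00851), control 4 (0.0365), treated 2 (0.0242), treated 3 (0.0398) or treated 4 (0.0365). Over all 8 libraries it was 0.924 with an estimated correlation, and it was 0.458 without treated 1. The count of falls was 4 without control 1 or treated 4 and 3 without treated 3.

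Several fetal and injury genes rose. Of 19 genes in the list of oncofetal, injury and p53 target genes 9 rose and 2 fell, with 11 higher and 2 lower when adjusted over the list alone. The largest rises were in genes of fetal liver, Afp, Gpc3, Igf2 (33.1 ± 27.3 to 435 ± 196 CPM, 3.71 on the log2 scale) and the imprinted RNA H19 (304 ± 205 to 1037 ± 344 CPM, 1.77). The p53 targets Phlda3, Trp53inp1 and Cdkn1a rose by 0.79, 0.78 and 0.76. Cpe, carboxypeptidase E, fell by 2.11 and the keratin gene Krt23 by 0.99. Camera passed upward (adjusted p = 0.0177), and adjusted p = 0.757 with an estimated correlation. A single gene of the list fell without control 1, 2 or 4 or treated 2 or 4. Of 22 cell cycle genes 7 fell and 1 rose, also when adjusted over the list alone. The mitotic genes Ccnb2 and Plk1 fell by 1.83 and 1.25, and Ccnd1, the cyclin of cell cycle entry, rose by 1.08. Camera passed downward (adjusted p = 0.0167), and adjusted p = 0.924 with an estimated correlation. This call ended without control 3 (adjusted p = 0.263), where 3 genes rose. Genes that fell numbered 4 without control 2 or treated 2 and 3 without treated 3.

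Acute phase genes were more often higher. Of 23 genes 10 rose and 2 fell, with 12 higher and 4 lower when adjusted over the list alone. The largest changes were in genes of metal handling, Hamp, the iron hormone hepcidin (62.9 ± 35.4 to 595 ± 347 CPM, 3.24 on the log2 scale), and the metallothioneins Mt2 (94 ± 26.7 to 786 ± 288 CPM, 3.06) and Mt1 (2.57). Crp fell by 1.24. Of the serum amyloid A genes, Saa1 and Saa2 had log2 fold changes of 0.40 and 0.14 and did not pass, and Saa3 rose (edgeR adjusted p = 0.0267), a call lost without control 1 (0.0659), control 2 (0.0678), treated 2 (0.0611) or treated 3 (0.0828). Camera passed upward (adjusted p = 0.0331), and adjusted p = 0.757 with an estimated correlation. The call ended without control 4 (adjusted p = 0.0532) or treated 1 (0.068). The number that rose was 5 without control 1 or 2 or treated 2, and 6 without control 4 or treated 3. The count of falls was 1 without control 2 or treated 3 and 4 with DESeq2 and limma voom.

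Some interferon-stimulated genes fell. Of 24 genes 6 fell and 18 did not pass, also when adjusted over the list alone (median log2 fold change -0.42). Ifit1 fell from 9.26 ± 2.16 to 4.04 ± 0.956 CPM, and Rsad2, an antiviral enzyme, from 24.1 ± 3.69 to 15.1 ± 3.15 CPM. Camera passed downward (adjusted p = 0.000691), and adjusted p = 0.757 with an estimated correlation. Genes that fell numbered 13 without treated 1, 18 with limma voom, 3 without control 2 or 4 and 2 without treated 2. Of 29 genes of inflammation 3 rose and 4 fell, with 7 higher and 4 lower when adjusted over the list alone. The neutrophil chemokine gene Cxcl1 rose from 7.52 ± 1.9 to 38.4 ± 16 CPM, and Cd9 fell by 0.97. Tnf had a log2 fold change of 0.55 ± 0.32 SE (edgeR adjusted p = 0.231). Trem2, a receptor of lipid-laden macrophages, had one of 1.28 ± 0.45 SE (edgeR adjusted p = 0.0634), and it passed without control 3 (1.64, adjusted p = 0.0269), without treated 1 (1.59, 0.00311) and with limma voom (0.00459). The camera test gave adjusted p = 0.351 for inflammation, 0.924 with an estimated correlation, and 0.00596 upward at the preset correlation without control 3 and treated 1 together. The number that rose was 11 without treated 1 and with limma voom, 8 without control 3, 6 with DESeq2 and 1 without control 1 or 2 or treated 2 or 3. The count of falls was 2 without control 2 or treated 2, 3 or 4.

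Of the markers of blood and immune cells, some of those of neutrophils rose, at low levels. Of 8 neutrophil markers 3 rose, 5 when adjusted over the list alone, and their summed level was 13.1 CPM in controls and 32.3 CPM in treated livers. Retnlg rose from 0.417 ± 0.157 to 2.14 ± 1.19 CPM. Camera passed upward (adjusted p = 0.0164), and adjusted p = 0.757 with an estimated correlation. The number that rose was 7 without treated 1 and with limma voom, 6 without control 3 and with DESeq2, and 1 without control 1, 2 or 4 or treated 2 and with the filter at 5 CPM. Of 15 Kupffer cell markers 1 rose and 1 fell, also when adjusted over the list alone. Emr1, which encodes F4/80, fell by 0.47. Cd5l had a log2 fold change of 0.69 (edgeR adjusted p = 0.0312), a call that held only without treated 1 among the 8 fits with a library left out (adjusted p up to 0.0881 in the others). Without treated 1, 6 Kupffer markers rose and 2 fell, 2 rose without control 3 and 2 fell without control 4, and camera over all 8 libraries gave adjusted p = 0.826. None of 13 lymphocyte markers passed in edgeR, 1 had an unadjusted p below 0.05, and 0 passed with DESeq2 and 1 with limma voom (camera adjusted p = 0.826). None of 6 red cell transcripts passed, 1 had an unadjusted p below 0.05, and 0 passed with DESeq2 and 1 with limma voom (camera adjusted p = 0.535); 1 rose and 1 fell without treated 1. Hba-a2 stood at 1317 ± 319 and 1497 ± 391 CPM and Hbb-bs at 900 ± 222 and 999 ± 162 CPM in control and treated livers.

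Genes of the extracellular matrix showed a wide spread within the control group. Of 32 fibrosis genes 1 rose, fibronectin Fn1 (1273 ± 228 to 1926 ± 156 CPM, log2 fold change 0.60, edgeR adjusted p = 0.0163). Its adjusted p was 0.0505 without control 2, and 0 of the genes passed when adjusted over the list alone, where edgeR had 2 higher and 4 lower at an unadjusted p below 0.05. Col1a1, the main fibrillar collagen, stood at 971 CPM in control 3 against 108 to 182 in the other controls and 118 ± 27.8 in treated livers (log2 fold change -1.55 ± 0.65 SE, edgeR adjusted p = 0.105). With 1 library left out the log2 fold change of Col1a1 ranged from -1.829 to -0.225. Acta2, a marker of activated stellate cells, stood at 83.6 CPM in control 3 against 9.48 to 20.8 in the others, and its log2 fold change of -1.03 (edgeR adjusted p = 0.24) became 0.14 without control 3 (adjusted p = 0.731). By camera the list had adjusted p = 0.539, with a median of -0.38. Without control 3, 6 of the fibrosis genes rose. Without treated 1, 3 rose and 1 fell, with DESeq2 1 rose and 1 fell, and with limma voom 6 rose and 1 fell. Of 16 stellate cell markers 1 rose (Reln, 0.68, edgeR adjusted p = 0.0251), and 0 passed when adjusted over the list alone, with 5 at an unadjusted p below 0.05. The Reln call held without control 3 or treated 1 and ended in the other 6 fits with a library left out (adjusted p up to 0.074). Without control 3, 4 stellate markers rose and 1 fell, and without treated 1, 6 rose and 1 fell. With camera the adjusted p was 0.464 (median 0.28, mean -0.04), 0.924 with an estimated correlation, and 0.0376 upward at the preset correlation without control 3 and treated 1 together.

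Few genes of the remaining cell type lists passed. Of 16 endothelial markers 1 fell (Kdr, -0.80, edgeR adjusted p = 0.0426), 0 when adjusted over the list alone, with 6 at an unadjusted p below 0.05. The call of Kdr held only without treated 1 among the 8 fits with a library left out (adjusted p up to 0.114 in the others). Without treated 1, 5 fell and camera passed downward (adjusted p = 0.0311), as it did without treated 2 (0.0359) and, with 6 lower, without control 3 and treated 1 together (0.0403), against 0.156 over all 8 libraries, and 0.924 there with an estimated correlation. Without control 1, 2, 3 or 4 or treated 3 or 4, 0 fell, and without control 3 1 rose; with limma voom 1 rose and 4 fell. Of 13 bile duct markers 1 rose and 2 fell, also when adjusted over the list alone, and camera gave adjusted p = 0.826. Sox9 had a log2 fold change of 1.52 (edgeR adjusted p = 0.0275) and lost the call without control 1 (0.0703), control 4 (0.0746), treated 2 (0.0734) or treated 3 (0.0757), with 2 markers higher without control 3 or treated 1 and 6 higher without both. Slc4a2 fell by 0.35 and lost the call without treated 2 (0.0577) or treated 3 (0.0548), and Spp1, osteopontin, by 1.32 with a call that ended without control 2 (0.0721), treated 2 (0.0798), treated 3 (0.0981) or treated 4 (0.0675). Control 3 had 1348 CPM of Spp1 against 306 to 679 in the other controls. None of 5 adipocyte markers passed, 1 had an unadjusted p below 0.05, and 1 passed with DESeq2, 2 with limma voom and 2 without treated 1 (camera adjusted p = 0.795, median -0.20, mean 0.26). Car3 stood at 724 ± 126 CPM in controls and 631 ± 697 CPM in treated livers, with 1657 CPM in treated 1. Of 5 pancreas and gut transcripts, Amy2a5 rose and Fabp2, which liver also expresses, fell, also when adjusted over the list alone (camera adjusted p = 0.826, median -0.46, mean 1.70).

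Stress response genes split. Of 23 genes of the unfolded protein and integrated stress responses 6 rose and 4 fell, with 6 higher and 5 lower when adjusted over the list alone. Chac1 and Trib3, targets of the transcription factor ATF4, rose by 1.24 and 1.02 on the log2 scale and Herpud1 by 0.93, while the chaperone genes Dnajc3 and Pdia6 fell by 0.84 and 0.45. The camera test gave adjusted p = 0.826 (median -0.04, mean 0.13), and 2 genes fell without treated 2 or 3. Of 25 antioxidant genes 4 rose and 4 fell, also when adjusted over the list alone. Nqo1 and Ces2a rose by 1.26 and 1.30 and Pgd, of the pentose phosphate pathway, fell by 0.81. By camera the list had adjusted p = 0.826 (median -0.10, mean 0.09, direction downward), and 2 genes fell without control 2 or treated 2, 3 or 4.

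Immediate early genes, which respond to handling within minutes, rose in part. Of 18 genes 8 rose, 9 when adjusted over the list alone. Egr1 rose from 18.7 ± 7.54 to 54.5 ± 27 CPM, Btg2 from 38 ± 4.21 to 104 ± 44.5 CPM and Junb from 49.4 ± 7.28 to 114 ± 48 CPM. Camera passed upward (adjusted p = 0.000861), and adjusted p = 0.757 with an estimated correlation. The number that rose was 4 without control 1 or 2 or treated 3, 5 without treated 2 or 4 and 14 with limma voom. Of 18 clock genes 5 rose and 3 fell, with 7 higher and 3 lower when adjusted over the list alone. Ciart rose by 1.71 and Per1 by 1.12, and Dbp had a log2 fold change of -0.91 (edgeR adjusted p = 0.0158), with 0.052 without treated 3. With camera the adjusted p was 0.357. The number that rose was 3 without treated 4 and 8 with limma voom, and the number that fell was 1 without control 1 or treated 2 and 0 without treated 3. Of 4 Y-linked genes tested 2 fell, 3 when adjusted over the list alone. Ddx3y, an RNA helicase gene, fell from 82.2 ± 6.86 to 49.8 ± 5.18 CPM. Eif2s3y had a log2 fold change of -0.37 (edgeR adjusted p = 0.0174) and lost the call without control 1 (0.0586), control 2 (0.0568), control 4 (0.066) or treated 3 (0.0515).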

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

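The tests of hepatocyte share, fasting, time of day, pancreas RNA, sex and Zhx2 were chosen only after the results were seen; the tests of control RNA, of a smaller knockdown and of other splits were written before their results were seen.

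In 21 of 256 groups of 4 values, 1 library lay far from the other 3, with a gap that took most of the range of the group. Chance gives about 13 such groups, and 14 of the 21 were in treated 1 and 5 in control 3. In treated 1 (CPM, range of the other 3 in brackets) Fads1 was 59.6 (35.9 to 37.2), Agpat3 238 (167 to 176), Acot1 38.9 (11.2 to 15.6), Sar1b 178 (101 to 106), Slc10a1 110 (39.8 to 42.6), Cyp2b9 109 (11.5 to 24.4), Rhbg 10.1 (3.04 to 3.67), Etnppl 134 (77.5 to 83.8), Kdr 32.3 (13.7 to 16.3) and Fasn 1210 (224 to 381), all high. Abca1 was 271 (366 to 377), Apoa5 1000 (1320 to 1380), Ppp1r15a 15 (21.8 to 22.1) and Cpe 2.51 (5.9 to 6.56), all low. In control 3 Igfbp1 was 239 (50.6 to 57.9), Col1a1 971 (108 to 182) and Acta2 83.6 (9.48 to 20.8), and Chrna4 was 3.33 (23.2 to 26.3) and Sar1b 172 (253 to 260). Rsad2 was 29.6 in control 2 (21.9 to 22.7) and Oat 703 in control 1 (313 to 363).

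The number of genes that changed, 3411, was reached by 1 of the 35 splits of the 8 libraries into 4 and 4, the real one. With 35 splits the test could give no smaller share, so it cannot exclude chance. Every other split puts treated and control libraries in the same group, which adds their difference to the spread within groups. The test also says nothing about cage or batch. The highest other split, which exchanges control 3 and treated 1, gave 1454, and the remaining splits gave 0 in edgeR. That split follows the position of these 2 libraries, which lie nearest to the other group on the first principal component.

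Of 47 sterol and lipogenic genes 44 fell (median of all -1.65), though neither list passed camera with an estimated correlation (adjusted p = 0.757). A smaller share of hepatocytes was argued against by the hepatocyte markers, whose median was -0.11 (SD 0.52). Fasting or less food cannot be told apart: fatty acid oxidation genes, which fasting induces, had a list mean that differed by -0.47 (SE 0.16, both over mice), but Irs2 (1.46), Igfbp1 (2.23), Igfbp2 (2.55) and Angptl4 (0.55) rose and Gck fell (-1.16) as in fasting, with the calls of Igfbp1 and Gck lost without control 1, 2 or 4 or treated 2, 3 or 4. A difference in time of day cannot be told apart either. Of 6 clock outputs 2 fell, Dbp (-0.91) and Nr1d2 (-0.27), while Ciart rose (1.71). These outputs need not peak at the same hour, so opposite moves do not count against a shift in time. Without treated 3 no clock gene passed as lower, though Dbp stayed at -0.87 (edgeR adjusted p = 0.052). As a hypothesis, less Dgat2 may lower the activity of SREBP in hepatocytes; effects of the siRNA outside Dgat2 stay open, since 1 siRNA and 1 control were used.

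Genes low in controls rose steeply, among them Fmo3 and Amy2a5 (0.234 and 0.166 CPM in controls), and so did Gpc3 (7.38 CPM) and Afp (89.7 CPM). RNA of pancreas was argued against by 8 acinar genes of the pancreas, whose sum was 0.0987% of Amy2a5 (0.335 against 339 CPM). No gene particular to salivary gland was tested, so RNA of that gland stays open. Female mice were argued against by the Y-linked genes, with at least 147 counts in each treated library, and by Xist, with at most 16 counts in any library. A fall of Zhx2 mRNA, a repressor of Afp, H19 and Gpc3, was bounded at -0.32 on the log2 scale (0 ± 0.14 SE). A return of hepatocytes toward a fetal pattern remains possible as a hypothesis, and activity of the repressor protein was not measured.

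Treated 1 shifted less than the other treated libraries, with a slope of 0.59 over 1184 genes against 0.83 to 1.09. These genes were called, with a change of at least 1 on the log2 scale, in the fit without treated 1. That choice favours the other treated libraries, so the size of the gap is uncertain. The first principal component, over all tested genes, also placed treated 1 nearest to the controls. Control RNA mixed into this library was argued against by Dgat2, which stood at 49.6 CPM in treated 1 against 631 to 667 CPM in controls. This level allows 2.67% of control RNA if the mouse's own Dgat2 was no lower than the lowest of the other treated libraries. A lower level of its own would allow somewhat more. The shift of the same genes needs a median of 49.6% (lower quartile 20.8%), which their choice may raise. A smaller knockdown cannot be told apart, because the Dgat2 shift of this library was 0.89 of that of the others, near the bound of 0.9 set for the test. A later response or a milder disease in this mouse may also apply, and neither was tested.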

How the results depend on the processing

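The fit without control 3 and treated 1 together was chosen only after the results were seen. The 3411 changed genes became 5576 with limma voom (2729 higher, 2847 lower) and 5859 without control 3 and treated 1 together (2893 and 2966); leaving out 1 library gave 2060 to 4818 genes (1043 to 2323 higher, 1017 to 2495 lower). All 8 fits with 1 library left out had fewer degrees of freedom, yet the count was higher without control 3 (3631) or treated 1 (4818). The cause of the lower and of the higher counts was not tested. The count stayed within 1.5 times with RLE factors (3428), no filter (3156), a filter at 5 CPM (3125), DESeq2 (4206) and unrounded counts (3411). The Dgat2 log2 fold change was -4.18 to -3.97 with 1 library left out. Of 12 gene lists past the camera threshold, 0 passed with an estimated correlation, also at an unadjusted p below 0.05. With 1 library left out 11 to 13 lists passed, some of them outside the 12, such as the list of drug metabolism. Of 111 named genes past the threshold besides Dgat2, 0 to 25 lost it with 1 library left out and none reversed. Reversals occurred in genes that had not passed. Acta2 became 0.137 without control 3 (range -1.317 to 0.137) and 0.046 without control 3 and treated 1 together. Car3 ranged from -1.33 to 0.138, with 0.049 without treated 3, and Hbb-bs from -0.002 to 0.246; the cause was not tested.

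Libraries of the 2 groups share replicate numbers only. The correlation of same-numbered libraries was 0.35, 0, 0.05 and -0.06, and only pair 1 correlated best with its own number. The replicate block gave 3550 genes (1711 higher, 1839 lower), 12 lists and -4.06 for Dgat2; among named genes the call of Spp1 was lost and those of Srebf1 (adjusted p = 0.0282) and Trem2 (0.0084) were gained. It moved some list counts by over 1.5 times, as in lipid droplets (8 lower instead of 4). On simulated data 19.4% of changes of 0.5 on the log2 scale were recovered, with fewer genes changed than in the data, so the share need not carry over.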

Other observations

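The lists of liver X receptor targets, imprinted genes, small nucleolar RNA host genes and MHC class I genes were chosen only after the results were seen, and camera p values here are not adjusted over lists; the tests of decay factors, ribosomal proteins and siRNA seeds were written before their results were seen.

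Host genes of small nucleolar RNAs, whose introns carry the guides for ribosomal RNA modification, rose in most cases. Of 13 such genes 10 rose in edgeR (median log2 fold change 1.47). Snhg4 rose by 3.31, Snhg7 by 2.55, Snhg3 by 2.40, Snhg5 by 1.65 and Gas5 by 0.61. Some MHC class I genes fell. Of 19 genes of presentation 7 fell and 1 rose. H2-Q10, a secreted class I protein of liver, fell by 1.71, H2-K1 by 0.92, Tapbp, which loads peptide, by 0.61 and B2m by 0.59, while Nlrc5, the activator of this class, rose by 1.19. H2-Q genes share reads, so their values are uncertain. Of 15 imprinted genes 4 rose, Igf2, H19, Peg3 (1.65) and Igf2r (0.78), and 2 fell, Mest (-1.60) and Gnas (-0.66). The rise of Peg3 (edgeR adjusted p = 0.0401) was not shared by treated 1. That library had 3.303 CPM, below the controls (4.748 to 5.599), against 12.351 to 31.725 in the other treated livers. Whether the call of Peg3 held with a library left out was not examined.

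The host genes gave camera p = 2.25e-07, and p = 0.0829 with an estimated correlation, but the list was drawn up after their rise was seen, so this test cannot stand on its own. Many are targets of nonsense-mediated decay, so weaker decay might raise them, and decay factors, several of which the pathway holds down, were tested as a list. Of 12 factors 8 rose, such as Smg9 (0.72) and Upf3b (0.64), and Upf1 fell (-0.31), with camera p = 0.0137 upward and p = 0.0869 with an estimated correlation. A wider rise of the translation machinery was not shown. Of 39 ribosomal protein genes 0 were higher and 2 lower in edgeR, with camera p = 0.0514 downward and p = 0.692 with an estimated correlation. The downward lean depends in part on treated 1, the lowest treated library for many of them. Examples are Rplp1 (318 CPM against 357 to 436 in the other treated livers) and Rpl14 (189 against 233 to 276). The list was not tested without treated 1. Decay itself was not measured.

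MHC class I genes gave camera p = 0.000635 downward, and p = 0.235 with an estimated correlation, on a list drawn up after falls were seen, so this test cannot stand on its own either. Imprinted genes gave camera p = 0.188 upward, and p = 0.298 with an estimated correlation, so a shared rise of the whole group was not shown.

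The list of liver X receptor targets passed upward (camera p = 0.0142, and p = 0.042 with an estimated correlation). In edgeR 6 of 14 rose, Abcg8, Abcg5, Abcg1 (0.92), Abca1, Cd5l and Mylip (0.57), and 0 fell. For Abcg1 (37.4 CPM), Cd5l (366 CPM) and Mylip (20.9 CPM) treated 1 lay within the range of the controls. As given above, the call of Cd5l held only without treated 1 among the 8 fits with a library left out. Cyp7a1 (-0.80, edgeR adjusted p = 0.134) and Nr1h3 (-0.32, 0.0649) leaned down without passing. The lipogenic genes Srebf1 (-0.53, edgeR adjusted p = 0.0727), Fasn (-2.35) and Scd1 (-1.57) were not on the list. Several of the 6 had been seen to rise before the list was written, so the test cannot stand on its own. As a hypothesis, more sterol ligand may reach the receptor while SREBP2 targets fall; sterols were not measured.

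An siRNA can lower other transcripts through pairing of its seed with their 3' UTRs. Among 13065 genes with an annotated 3' UTR (94.5% of those tested), each 7-mer of the Dgat2 transcript was scored. The score rests on ranks of the fold changes, after removal of their trend with the length and GC content of the UTR. Within 30 nucleotides of position 1473 the lowest score was z = -4.56 for AAAAGAA at position 1491 (chromosome 7, 99154423 to 99154429). This was also the lowest score on the whole transcript. The 2.8% of windows that reached as low are those that hold this 7-mer, so the test could give no smaller share. The 3725 genes with this 7-mer differed by a median of -0.064 on the log2 scale. It had the lowest score of 16370 7-mers, though the highest score, 4.69, was larger in size and no seed effect gives that direction. Of 7 rearrangements scored, itself among them, AAAGAAA (-3.98) and AAGAAAA (-2.66) were low too, while GAAAAAA was highest at -0.59. AAAGAAA also shares most of its sequence with AAAAGAA. A-rich 3' UTRs may account for part of the low score, which these values do not settle. The guide sequence is not given in the sources used here, and the seed effect is a hypothesis that it could settle.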
